A study of Mus musculus with 12 samples.

How the data were processed

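Gene expression was measured in total RNA of mouse embryonic stem cells and of cells at day 9 and day 14 of differentiation on crosslinked elastin-like polypeptide, with 4 arrays per group. Per the labels the RNA was copied into Cy3-labelled cRNA and read on 1-colour Agilent arrays. The same growth text is repeated for every sample, and the day at which the mESC samples were taken is not given in the sources used here. Per the file headers each array was extracted on its own with Agilent Feature Extraction 12, which gave the deposited processed signal as an intensity: the brightness of a spot after background subtraction and spatial detrending, on a linear scale and not scaled between arrays. The deposited median signal and local background of each spot are intensities with no correction, per the file headers. The other deposited columns used were flags of 0 or 1, per the file headers, for spots well above background, saturated spots and spots that stand out from their replicates. The value table of the series held the same intensity values as the array files, as deposited, with 0 differences.

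Each array held 45018 spots, of which 43379 were not controls and carried 41174 probes. Control spots and spots marked as outliers were left out, no spot was saturated, and spots of the same probe were averaged on the log2 scale. The log2 processed signal of each array was reduced by its 75th percentile. A probe was tested if it was well above background on at least 3 of the 4 arrays of at least 1 group, which 28369 probes met. Probes were named through their RefSeq accessions in an annotation of GRCm38.p6, which named 28223 probes, and 12951 were not named here. The array's own annotation refers to the older build mm9, so no positions are given. The tested probe with the highest mean stood for a gene, which gave 20869 genes. Probes without a name were grouped by accession, and each accession is counted as a gene here, although several may belong to 1 gene. Of the genes called at day 9 against mESC, at day 14 against mESC and between the days, 6589, 7633 and 2413 were named. Among called genes with other tested probes, a probe was called the opposite way in 45 of 2273 at day 9 and 43 of 2608 at day 14 against mESC, and in 0 of 619 between the days. Of the named genes 82, 66 and 48 had other probes in these comparisons, and in 10, 5 and 15 of them a probe was not called the same. In 33, 31 and 5 another probe lay more than 2 on the log2 scale from the value given, so the sizes of these changes depend on the probe.

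Differences between groups were tested with limma 3.58.1 in R 4.3.3, with group means over all 12 arrays and moderated variances, and p-values were adjusted by the Benjamini-Hochberg method over genes. A gene was called at an adjusted p under 0.05 with an absolute log2 fold change of at least 1. The tests are two-sided. A gene with no probe above background on any array of a group was given as a bound, its mean in the other group against the dimmest well-above-background signal of each array of the dim group. Of the called genes 2079, 2234 and 580 were below background throughout 1 group at day 9 against mESC, day 14 against mESC and day 14 against day 9, and 41, 9 and 22 throughout both.

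The 48 gene lists of cell states, cell types and pathways were written from general knowledge and hold 838 genes, of which 60 were not tested. Each list was tested in the 3 comparisons with the camera test of limma at a preset correlation between genes of 0.01, and p-values were adjusted over the 144 tests. Of these, 78 were called, 61 upward and 17 downward, and 10 were also called with an estimated correlation: smooth muscle, epithelial to mesenchymal transition, Wnt pathway and BMP and TGF-beta pathway at both days against mESC, and macrophage and ribosome biogenesis between the days. Median, mean and test differed in sign in 14 list tests, none of them called.

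Genes were named by a rule. It took the 8 called genes with the largest change in each direction that had a proper symbol. They also had to be above background, by any of their probes, on at least 1 array of each group. The rule also took 26 key genes in the comparison of day 14 with mESC, and in the other comparisons where called. Of each list it took up to 4 called members with the largest change, or, where none was called, up to 2 with the highest mean signal. Genes named outside the rule are said to have been chosen after their values were seen. The text gives the values of only a part of the genes that the rule takes, picked with the values at hand, and 2 of the others were left out for another reason, as they were not to be reported.

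Slide and scan coincide with group, so neither could enter the model. Alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, the series table, no filter, probes above background on all arrays, the mean over probes, only the 8 arrays compared, an intensity trend with robust variances, array weights, a replicate block, no fold threshold, a test against a log2 fold change of 1 and leaving out each array in turn. Normexp used the median signal of the spots, since the files hold no mean signal. The median of all genes was −0.16 at day 9 and −0.19 at day 14 against mESC, and −0.09 between the days. It moved to −0.06 at day 14 with median scaling, and to 0.10 at day 14 and 0.16 between the days with normexp.

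On simulated data with 200 changed genes among 20869, 50 at each size, the model recovered 90% at day 9, 82% at day 14 and 90% between the days of those changed by a log2 of 1.2, and 98%, 98% and 100% of those changed by 3, with 7, 3 and 5 calls among unchanged genes. The R package data.table was used in version 1.17.8, and plots were drawn with Python 3.11.15 and matplotlib 3.10.9.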

Results

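Total RNA of mouse cells was measured on 12 one-colour Agilent arrays, which read each gene as the brightness of Cy3-labelled RNA bound to its probes. There were 3 groups of 4 arrays each: mouse embryonic stem cells (mESC), and cells at day 9 and day 14 of a differentiation on plates coated with crosslinked elastin-like polypeptide, a protein polymer modelled on elastin. The labels describe a medium without LIF, the factor that keeps mouse stem cells undifferentiated, followed by a serum-replacement medium. The design text names the comparison of stem cells with cardiomyocyte differentiation at both days. The labels do not say whether the 4 replicates of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical. Each group lay on its own slide and scan, so slide and group cannot be told apart in any comparison.

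The 75th percentile of signal was 345.9 to 386.2 on the mESC arrays, 395.1 to 438.4 at day 9 and 463.4 to 507.7 at day 14, and 59.5% to 67.9% of probes were well above background. Of 20869 genes tested, 15555 carried a gene symbol. Arrays of the same group correlated at 0.9925 or more across genes, and arrays of different groups at 0.8405 or more, where genes are not independent replicates. The first principal component carried 82.1% of the variance and parted the mESC arrays from the others, and the second carried 13.7% and parted day 9 from day 14. The number of arrays limits the precision of every value given here. Changes are log2 fold changes ± SE with n = 4 arrays in each group, and a gene is said to rise or fall only at an adjusted p under 0.05 with a change of at least 1 on the log2 scale. The SE rests on 1 moderated variance per gene, shared by the 3 groups. Heart genes such as Myh6 spread most at day 9. Their SE can therefore be too small for comparisons with day 9 and too large for day 14 against mESC. Where no probe of a gene was above background on any array of a group, its change is given as a bound, "at least N-fold". The bound is computed against the dimmest signal that was well above background. It uses the probe that stands for the gene, and another probe can lie below it.

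At day 9 most tested genes of the pluripotency network had fallen and most sarcomere genes had risen relative to mESC. Neither list kept its call with an estimated correlation. Nanog and Pou5f1, transcription factors that maintain pluripotency, changed by −7.24 ± 0.11 and −5.83 ± 0.21. The sarcomere genes Actc1 (cardiac alpha-actin), Myh6 (alpha myosin heavy chain) and Tnnt2 (cardiac troponin T) rose by 8.49 ± 0.18, 7.28 ± 0.31 and 6.70 ± 0.21. Collagens and other genes of fibroblasts rose with them: Col3a1 was at least 2560-fold and Postn at least 2120-fold higher. Across all genes 8562 were called, 4178 higher and 4384 lower, and 2329 of them changed at least 8-fold on the fitted scale.

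Of the 25 tested genes of the pluripotency network, 23 fell and none rose (adjusted p = 5.62e-07, and adjusted p = 0.143 with an estimated correlation). Beside Nanog these included Zfp42 (−6.52 ± 0.12), Esrrb (−6.36 ± 0.13) and Gdf3 (−6.18 ± 0.16), and Sox2 fell by 4.26 ± 0.19. Genes of the two-cell-like state and of germ cells fell in 11 of 12 cases (adjusted p = 0.000276, and adjusted p = 0.215 with an estimated correlation). Dazl, an RNA-binding protein of germ cells, changed by −8.73 ± 0.30 and Zscan4c by −5.74 ± 0.13. In the primed epiblast list 3 genes rose and 4 fell of 10 (adjusted p = 0.797): Fgf5 was at least 10.9-fold higher, while Nodal fell by 5.08 ± 0.17. In the primitive streak list 6 rose and 4 fell of 15 (adjusted p = 0.556), with Pdgfra at 6.88 ± 0.06 and Eomes at −3.80 ± 0.19.

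Cardiac transcription factors rose in 16 of 23 cases and 1 fell (adjusted p = 0.000146, and adjusted p = 0.23 with an estimated correlation). Hand1 rose by 7.41 ± 0.18, Gata6 by 6.18 ± 0.07, Tbx5 by 5.54 ± 0.12, Tbx20 by 5.52 ± 0.07, Nkx2-5 by 4.04 ± 0.30 and Isl1, a factor of early heart progenitors, by 2.95 ± 0.24. Hand2 was at least 110-fold, Mef2c at least 71.0-fold and Gata4 at least 13.5-fold higher. Sarcomere genes rose in 25 of 27 cases and 1 fell (adjusted p = 8.06e-08, and adjusted p = 0.367 with an estimated correlation). Among them Ankrd1 was at least 381-fold higher, Myl3 rose by 8.99 ± 0.25, Myh7 by 6.24 ± 0.21, Myl7 by 5.32 ± 0.14, Myl2 by 5.28 ± 0.23 and Tnni3 by 2.72 ± 0.26; another probe of Myl3 moved by 1.78. Of the 23 genes of cardiac calcium handling and ion channels, 18 rose, 1 of them from levels below background in both groups, and none fell (adjusted p = 5.15e-06, and adjusted p = 0.23 with an estimated correlation). Jph2 was at least 123-fold higher, where another of its probes moved by 5 on the log2 scale. Hrc and Ryr2, the calcium release channel, rose by 5.09 ± 0.32 and 2.70 ± 0.26. In the list of cardiac hormones and fetal genes 9 of 10 rose (adjusted p = 4.19e-05, and adjusted p = 0.23 with an estimated correlation), and Nppa was at least 18.1-fold higher.

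**Figure D1:**
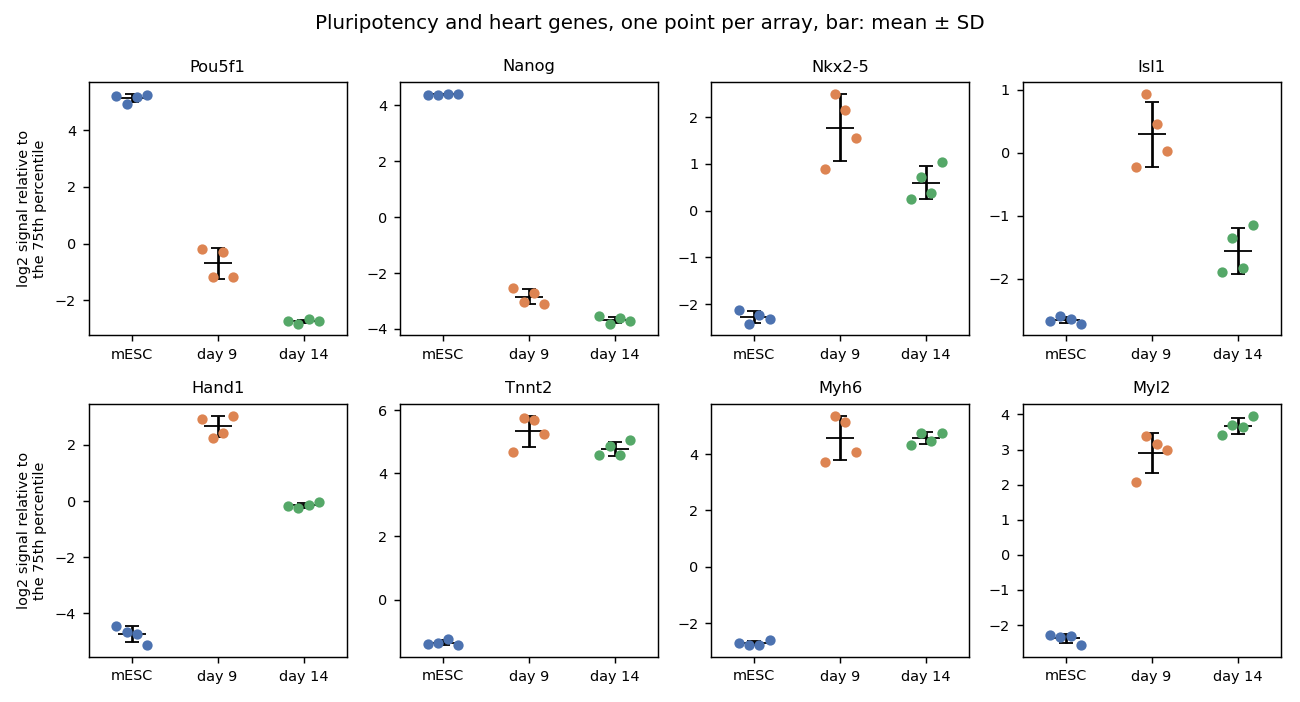
Log2 signal relative to each array's 75th percentile (vertical axes) of 8 genes, 1 point per array, with the mean and SD of the 4 arrays of mESC, day 9 and day 14. Nanog fell by 7.24 at day 9, Hand1 rose by 7.41 at day 9 and fell by 2.81 from day 9 to day 14, and the 4 day 9 arrays spread most in Myh6 (SD 0.79).

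Markers of other cell types moved beside the heart genes. Smooth muscle genes rose in 14 of 15 cases (adjusted p = 1.93e-06, and adjusted p = 0.0444 with an estimated correlation). Tagln stood at 6.34 ± 0.08 and Cnn1 at 6.03 ± 0.17. Fibroblast and interstitial collagen genes rose in 21 of 24 cases and 1 fell (adjusted p = 1.33e-08, and adjusted p = 0.23 with an estimated correlation). Elastic fibre genes rose in 13 of 16 cases and 2 fell (adjusted p = 3.15e-05, and adjusted p = 0.23 with an estimated correlation). Mfap2 rose by 9.24 ± 0.13, Fbn2 by 6.38 ± 0.24 and Fbn1 by 5.62 ± 0.10. Epicardium genes rose in 8 of 10 cases and 1 fell (adjusted p = 0.00502, and adjusted p = 0.232 with an estimated correlation): Wt1 was at least 62.1-fold and Tcf21 at least 76.2-fold higher. Endothelial genes rose in 13 of 19 cases and 3 fell (adjusted p = 0.0065, and adjusted p = 0.52 with an estimated correlation). Emcn was at least 70.0-fold higher and Vwf changed by −4.90 ± 0.09. In the blood and erythroid list 7 of 13 rose and 1 fell (adjusted p = 0.0396, and adjusted p = 0.473 with an estimated correlation). The embryonic globin gene Hbb-bh1 was at least 101-fold higher. The macrophage list was not called (adjusted p = 0.875). Of its 17 genes 2 were called higher and 4 lower, 1 of these from levels below background in both groups.

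Endoderm markers rose as well. In the visceral endoderm and liver list 15 of 21 rose, 1 of them from levels below background in both groups, and 1 fell (adjusted p = 0.000161, and adjusted p = 0.271 with an estimated correlation). The fetal serum protein gene Afp was at least 1610-fold higher and Spink1 rose by 8.35 ± 0.21. Parietal endoderm genes rose in 12 of 14 cases (adjusted p = 9.0e-06, and adjusted p = 0.143 with an estimated correlation). Of these 14 tested genes 9 also stood in another list and 12 were above background on all mESC arrays, so the list is not specific to that cell type. Genes of definitive endoderm and gut rose in 8 of 14 cases and 1 fell (adjusted p = 0.00724, and adjusted p = 0.394 with an estimated correlation). Foxa2 rose by 5.08 ± 0.19 and Cdx2 was at least 45.7-fold higher. The 18 lists for other cell types held 279 tested genes, of which 189 were also above background on all 4 mESC arrays and 61 stood in another list. Genes of the epithelial to mesenchymal transition rose in 10 of 12 cases and 1 fell (adjusted p = 0.000121, and adjusted p = 0.0417 with an estimated correlation). Tgfb2 stood at 7.31 ± 0.08 and the mesenchymal cadherin Cdh2 at 5.46 ± 0.10. Cell cycle genes fell in 15 of 29 cases and none rose (adjusted p = 1.4e-05, and adjusted p = 0.23 with an estimated correlation), with the replication gene Mcm3 at −1.85 ± 0.07.

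The largest changes among genes above background in both groups were those of the growth factor Igf2 (10.22 ± 0.06), Col4a6 (9.58 ± 0.12), the imprinted gene Nnat (9.43 ± 0.14) and Col6a3 (9.39 ± 0.29) upward, and of Spic (−9.54 ± 0.19), Dazl, Spp1, which encodes osteopontin (−8.55 ± 0.19), and Khdc3 (−8.35 ± 0.23) downward. Other probes of Col4a6 and Col6a3 moved by as little as 0.34 and 0.56 and were not called the same. Those of Col3a1 and Mfap2 moved by 4.35 and 4.78. Above background here means by any probe of a gene, which need not be the probe whose change is given. On probes above background on all arrays Col4a6 stood at 0.34 and was not called. All 207 named calls had an adjusted p of at most 0.000151. With the normexp background correction 4750 genes were called and 23 of the 207 named calls ended. Over 19 alternatives with the preset correlation the adjusted p of the blood list ran from 0.00699 to 0.383 and missed the threshold with quantile normalization, normexp and probes above background on all arrays, and in the last setting the epicardium list (0.000242 to 0.15) and the gut list (0.000835 to 0.0729) missed it too.

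At day 14 most tested genes of the pluripotency network were lower than in mESC. Most genes of the sarcomere, fibroblast, visceral endoderm and liver, and macrophage lists were higher. None of these lists kept its call with an estimated correlation. Pou5f1 changed by −7.88 ± 0.21 and Nanog by −8.07 ± 0.11. Myh6 rose by 7.27 ± 0.31, Tnnt2 by 6.13 ± 0.21 and Myl2, the regulatory light chain of ventricular muscle, by 6.06 ± 0.23. Alb, the serum albumin of the liver, rose by 12.29 ± 0.58, and Adgre1, which encodes the macrophage antigen F4/80, was at least 152-fold higher. Another probe of Adgre1 moved by only 2.38 on the log2 scale. In all, 9780 genes were called, 4749 higher and 5031 lower.

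Of the 26 key genes set for the study, 20 rose, 5 fell and 1 did neither. Those that fell were Pou5f1, Nanog, Zfp42 (−7.66 ± 0.12), Sox2 (−4.82 ± 0.19) and Mesp1, a factor of early heart mesoderm (−1.17 ± 0.15). T, a primitive streak factor, was not called at −0.79 ± 0.07. Of the transcription factors Gata6 rose by 5.97 ± 0.07, Tbx20 by 4.90 ± 0.07, Tbx5 by 4.68 ± 0.12, Hand1 by 4.59 ± 0.18, Nkx2-5 by 2.87 ± 0.30 and Isl1 by 1.10 ± 0.24, while Hand2 was at least 65.8-fold, Mef2c at least 63.9-fold and Gata4 at least 7.84-fold higher. Of the contractile and membrane genes Actc1 rose by 7.48 ± 0.18, Myh7 by 5.66 ± 0.21, Myl7 by 5.03 ± 0.14, Actn2 by 4.19 ± 0.32, Tnni3 by 3.68 ± 0.26, Gja1 by 3.09 ± 0.08 and Ryr2 by 2.24 ± 0.26, and Nppa was at least 35.6-fold higher.

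Sarcomere genes rose in 24 of 27 cases and none fell (adjusted p = 3.29e-07, and adjusted p = 0.394 with an estimated correlation), with Myl3 at 8.66 ± 0.25, or 1.44 on another probe. Cardiac transcription factors rose in 17 of 23 cases and 2 fell (adjusted p = 0.000484, and adjusted p = 0.262 with an estimated correlation). Calcium handling and ion channel genes rose in 20 of 23 cases (adjusted p = 1.01e-06, and adjusted p = 0.23 with an estimated correlation). Sln was at least 52.4-fold and Cacna1g at least 87.5-fold higher, where another probe of Cacna1g moved by 4.44 on the log2 scale. Cardiac hormone and fetal genes rose in 9 of 10 cases (adjusted p = 0.000144, and adjusted p = 0.262 with an estimated correlation), among them Corin, at least 30.4-fold higher. The pluripotency network fell in 24 of 25 cases (adjusted p = 2.46e-07, and adjusted p = 0.139 with an estimated correlation), with Esrrb at −8.12 ± 0.13. The two-cell-like and germ cell list fell in 11 of 12 (adjusted p = 0.000931, and adjusted p = 0.23 with an estimated correlation).

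**Figure D2:**
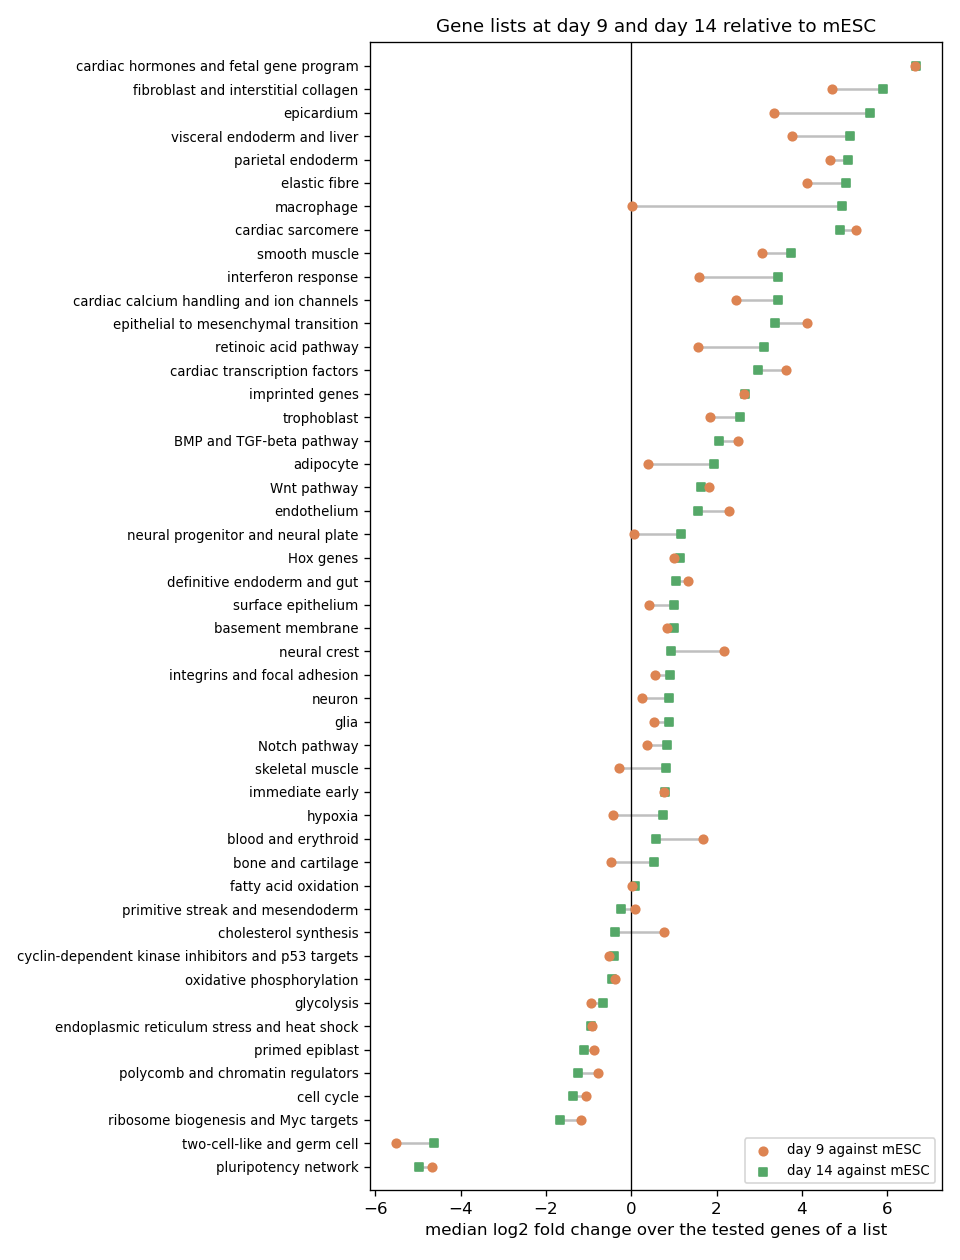
Median log2 fold change over the tested genes of each of the 48 lists (horizontal axis) at day 9 (circles) and day 14 (squares) against mESC, from fitted values. The sarcomere list stood at 5.28 and 4.91, and the macrophage list at 0.01 and 4.95, or 0.00 and 4.93 with genes below background in a group set to their bound. Other lists moved more at their bounds. The interferon list went from 1.59 and 3.45 to 0.97 and 1.48, and the visceral endoderm and liver list from 3.76 and 5.13 to 3.36 and 4.28.

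Fibroblast and interstitial collagen genes rose in 22 of 24 cases and 1 fell (adjusted p = 9.4e-09, and adjusted p = 0.23 with an estimated correlation). Dcn was at least 4270-fold and Lum at least 2870-fold higher. Elastic fibre genes rose in 15 of 16 cases (adjusted p = 3.64e-07, and adjusted p = 0.181 with an estimated correlation). Mfap4 rose by 6.80 ± 0.13 and Fbn2 by 6.72 ± 0.24, and the crosslinking enzyme Lox was at least 193-fold higher. Smooth muscle genes rose in 14 of 15 cases (adjusted p = 7.25e-07, and adjusted p = 0.0417 with an estimated correlation), Mylk by 6.68 ± 0.08. Epicardium genes rose in 8 of 10 (adjusted p = 0.000907, and adjusted p = 0.225 with an estimated correlation), Wt1 by at least 172-fold. Basement membrane genes rose in 8 of 16 cases and 1 fell (adjusted p = 0.0123, and adjusted p = 0.317 with an estimated correlation), Col4a1 by 5.33 ± 0.07. Integrin and focal adhesion genes rose in 13 of 26 cases and 3 fell (adjusted p = 0.01, and adjusted p = 0.15 with an estimated correlation), Itga8 by 4.27 ± 0.08.

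Macrophage genes rose in 16 of 17 cases and none fell (adjusted p = 3.64e-07, and adjusted p = 0.0813 with an estimated correlation). Tyrobp was at least 299-fold, C1qc at least 133-fold and Csf1r at least 64.8-fold higher, where another probe of Csf1r moved by 4.65 on the log2 scale. In the visceral endoderm and liver list 16 of 21 rose and 1 fell (adjusted p = 3.64e-05, and adjusted p = 0.23 with an estimated correlation). Afp was at least 4950-fold and Fgb at least 928-fold higher. Interferon response genes rose in 12 of 17 cases and 2 fell (adjusted p = 0.00481, and adjusted p = 0.23 with an estimated correlation). Ifih1 was at least 16.5-fold higher and Oas1a changed by −5.36 ± 0.31. Retinoic acid pathway genes rose in 9 of 14 cases (adjusted p = 0.00169, and adjusted p = 0.0582 with an estimated correlation), the dehydrogenase Aldh1a1 by 7.08 ± 0.09. In the endothelial list 10 rose and 3 fell of 19 (adjusted p = 0.101) and in the blood and erythroid list 5 rose and 2 fell of 13 (adjusted p = 0.163). Ptprc, the antigen CD45 of white blood cells, was 6.09 ± 0.17 higher. Cell cycle genes fell in 21 of 29 cases (adjusted p = 3.05e-06, and adjusted p = 0.215 with an estimated correlation), with Mcm3 at −2.36 ± 0.07. Genes of ribosome biogenesis and Myc targets fell in 14 of 18 cases and 1 rose (adjusted p = 7.01e-05, and adjusted p = 0.0561 with an estimated correlation): Dkc1 changed by −3.23 ± 0.06, while Myc itself rose by 3.71 ± 0.09.

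The largest changes among genes above background in both groups were, after Alb, those of Col6a3 (11.39 upward), Mfap2 and Col4a6 (10.41 upward), and downward those of Spic (−10.21), Triml1 (−8.43) and Morc1 (−8.40); other probes of Col6a3, Mfap2 and Col4a6 moved by as little as 2.57, 6.06 and 0.69. On probes above background on all arrays Col4a6 stood at 0.69 and was not called. All 207 named calls had an adjusted p of at most 0.00974. Isl1 lost its call with quantile normalization (0.88), with normexp (0.72) and without day 14 replicate 4 (0.96), Mesp1 moved to 0.02 with normexp, and T was called with quantile normalization (−1.05). With normexp 5835 genes were called. On probes above background on all arrays the interferon list was not called (adjusted p = 0.457, range over 19 alternatives 0.000144 to 0.457).

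From day 9 to day 14 macrophage genes, a part of the fibroblast and elastic fibre genes and several liver genes rose. Genes of cholesterol synthesis, the early heart factors Hand1 and Isl1 and an embryonic globin gene fell. Of the macrophage, fibroblast, elastic fibre and cholesterol lists only the first kept its call with an estimated correlation. The macrophage protease Ctss rose by 7.90 ± 0.26 and the liver proteins Ahsg and Alb by 9.85 ± 0.10 and 8.53 ± 0.58. Eln, the gene of elastin, rose by 3.15 ± 0.08. Hand1 changed by −2.81 ± 0.18, Isl1 by −1.85 ± 0.24 and Hbb-bh1 by −7.14 ± 0.55. Fewer genes were called than against mESC: 2880, of which 2126, or 73.8%, were higher and 754 lower. Without the fold threshold the balance turned: 5305 were higher, or 40.1%, and 7914 lower.

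All 17 macrophage genes rose (adjusted p = 8.47e-15, and adjusted p = 0.0417 with an estimated correlation). Their median was 4.65, or 4.63 with genes below background at day 9 set to their bound. Adgre1 was at least 199-fold, C1qc at least 175-fold and Cx3cr1 at least 50.7-fold higher. Other probes of Adgre1 and Cx3cr1 moved by only 2.91 and 2.39 on the log2 scale. Interferon response genes rose in 9 of 17 cases (adjusted p = 0.000265, and adjusted p = 0.177 with an estimated correlation), Oasl2 by 2.34 ± 0.17. In the visceral endoderm and liver list 9 rose and 6 fell of 21, the median was −0.14 and the mean 1.31, so these differed in sign, and the list was not called (adjusted p = 0.217). The fibrinogen gene Fgg rose by 5.12 ± 0.25. Neuron genes rose in 12 of 18 cases and 1 fell (adjusted p = 0.000898, and adjusted p = 0.42 with an estimated correlation), the microtubule protein gene Mapt by 2.70 ± 0.16. Against mESC the neuron list was not called at day 9 (7 higher, 5 lower, adjusted p = 0.544) or day 14 (9 higher, 5 lower, adjusted p = 0.137). Mapt stood below mESC at day 9 (−4.20 ± 0.16) and at day 14 (−1.50, a value chosen after it was seen). Adipocyte genes rose in 5 of 9 cases (adjusted p = 0.00174, and adjusted p = 0.143 with an estimated correlation), the fatty acid binding protein gene Fabp4 by 6.43 ± 0.08.

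**Figure D3:**
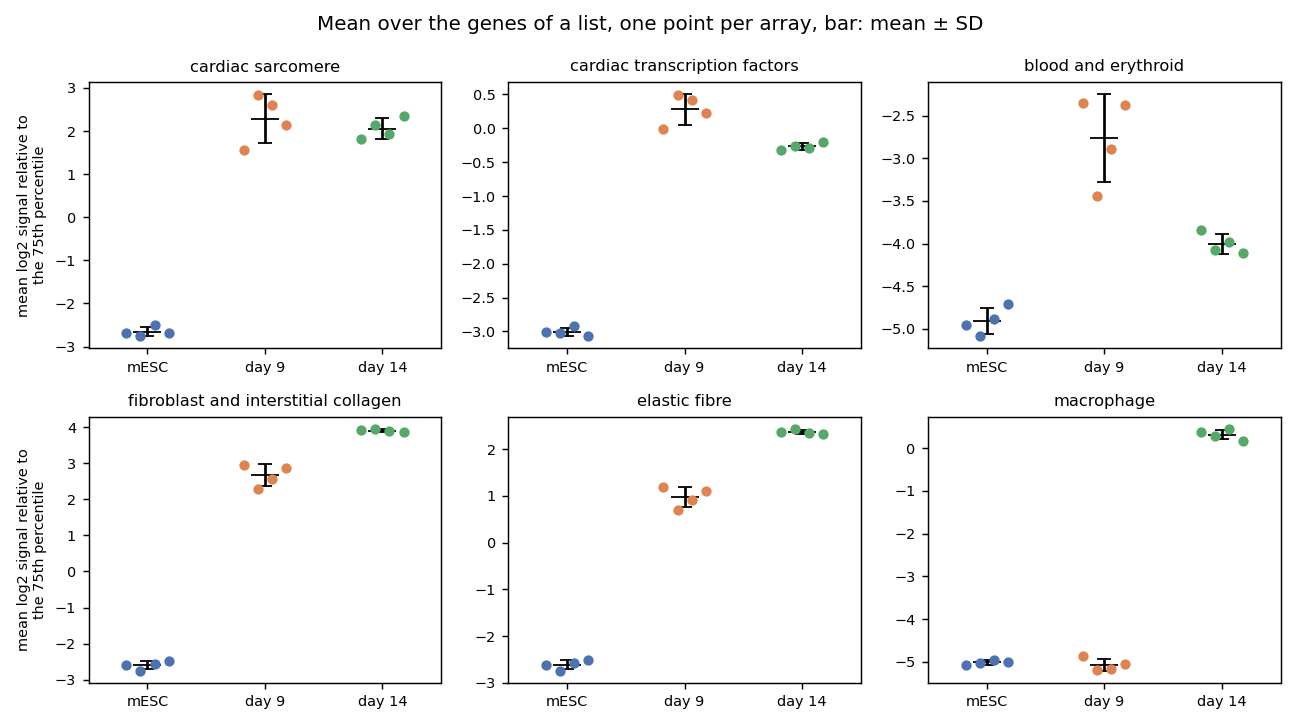
Mean log2 signal over the genes of 6 lists relative to each array's 75th percentile (vertical axes), 1 point per array, with the mean and SD of the 4 arrays of mESC, day 9 and day 14. The macrophage list lay between −5.18 and −4.88 on the day 9 arrays and between 0.18 and 0.45 on the day 14 arrays, and the sarcomere list spread from 1.56 to 2.85 at day 9.

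Fibroblast and interstitial collagen genes rose in 12 of 24 cases and 1 fell (adjusted p = 0.000484, and adjusted p = 0.474 with an estimated correlation), with Lox at 4.45 ± 0.43 and Col6a2 at 3.78 ± 0.06. Elastic fibre genes rose in 7 of 16 cases (adjusted p = 2.3e-05, and adjusted p = 0.23 with an estimated correlation), Ltbp2 by 4.92 ± 0.14 and Mfap4 by 1.79 ± 0.13. Epicardium genes rose in 6 of 10 cases (adjusted p = 0.00719, and adjusted p = 0.257 with an estimated correlation), the mesothelin gene Msln by 6.22 ± 0.13. Hypoxia genes rose in 6 of 15 cases (adjusted p = 8.55e-05, and adjusted p = 0.23 with an estimated correlation), Egln3 by 2.08 ± 0.17 and Car9 by 2.05 ± 0.06. Endothelial genes fell in 8 of 19 cases and none rose (adjusted p = 0.000386, and adjusted p = 0.394 with an estimated correlation), with Plvap at −2.85 ± 0.12 and Emcn at −1.81 ± 0.08. In the blood and erythroid list 6 of 13 fell and 1 rose (adjusted p = 0.338): Hba-x was at least 49.1-fold lower, while Ptprc rose by 5.17 ± 0.17.

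The sarcomere list was not called between the days (adjusted p = 0.544): 1 of 27 genes rose, Myom2 by 3.51 ± 0.17, and 4 fell, among them the slow troponin gene Tnni1 (−1.29 ± 0.19). Of the cardiac transcription factors 3 of 23 fell and none rose (adjusted p = 0.0921): Hand1, Isl1 and Nkx2-5 (−1.18 ± 0.30). This list was called lower with normexp (adjusted p = 0.00499), without day 9 replicate 1 (0.0229), with array weights (0.0327) and with no filter (0.0408). Calcium handling and ion channel genes rose in 8 of 23 cases (adjusted p = 0.0221, and adjusted p = 0.561 with an estimated correlation). Sln was at least 68.7-fold and Casq2 at least 14.4-fold higher, and Cacna1g and Pln rose by 2.97 ± 0.12 and 2.90 ± 0.35. Cardiac hormone and fetal genes showed 1 rise and 3 falls in 10 (adjusted p = 0.812), and smooth muscle genes 3 rises and 1 fall in 15 (adjusted p = 0.709), with Myh11, the smooth muscle myosin, 2.23 ± 0.17 higher. Genes of cholesterol synthesis fell in 14 of 17 cases (adjusted p = 1.14e-08, and adjusted p = 0.0606 with an estimated correlation), with Dhcr7 at −1.28 ± 0.05. At day 9 against mESC 4 of the 17 had risen (adjusted p = 1.4e-05, and adjusted p = 0.15 with an estimated correlation). Between the days 9 of 25 genes of the pluripotency network fell and 1 rose (adjusted p = 0.00921, and adjusted p = 0.386 with an estimated correlation), with Lin28a at −3.34 ± 0.21 and Pou5f1 at −2.04 ± 0.21.

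The calcium handling list was not called without day 9 replicate 1 (adjusted p = 0.0679), with array weights (adjusted p = 0.0696) or on probes above background on all arrays (adjusted p = 0.436, range over 19 alternatives 0.00265 to 0.436). Nkx2-5 was not called without day 9 replicate 2 (−0.94). All 162 named calls had an adjusted p of at most 0.00578; with normexp 1226 genes were called.

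Of the genes called at either day against mESC, 7269 were called in the same direction at both, 3593 higher and 3676 lower, where independent lists would share 2008. Both comparisons use the same mESC arrays: with these parted into separate pairs for the 2 days the number was 7064 to 7203. In simulations with unchanged groups it was 0. Those held no changed genes, so they do not measure how far the shared arrays raise the overlap among changed genes. Between the days 3263 of the shared falls and 2682 of the shared rises were not called again, while 668 genes rose at day 9 and rose further to day 14. A further 684 genes were called higher at day 14 against both other groups and were not called at day 9 against mESC. In all 144 list tests the numbers of genes called were the same when adjusted over the list alone.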

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

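Of the tests in this part, the test of the share of heart muscle cells was chosen only after the result was seen. For each comparison the 8 arrays were regrouped in all 35 ways into 4 and 4. Of these 35 splits 1, the real one, gave as many calls. The other splits mix the groups, so the difference between groups enters their spread and few calls can follow. The test cannot exclude chance differences between slides or cultures, since slide follows group and separate cultures are not stated. The real values were 8562, 9780 and 2880 genes for day 9 against mESC, day 14 against mESC and day 14 against day 9, and the highest of the other splits were 2, 0 and 1.

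Macrophage genes differed between the days: their median change from day 9 to day 14 was 4.65 by a test of the difference itself, and all 17 rose, 7 of which were also above background on all 4 mESC arrays and 1 of which stood in another list. A lift of dim probes on the day 14 slide was argued against, since 14013 probes of matched day 9 signal had a median change of −0.10 with a 95th percentile of 1.73, and 0.607% of them reached 4.65. A candidate explanation is that macrophages were present in the day 14 samples. A further macrophage list of 32 genes, added to the 48 lists, held no gene of the first. Of its 31 tested genes 30, or 96.8%, rose, with Trem2 at least 414-fold, Fcgr1 at least 91.1-fold and Mpeg1 7.10 higher. Of these, Trem2 and Fcgr1 were chosen after their values were seen. Genes below background on all day 9 arrays, such as Trem2 and Fcgr1, could hardly be called lower. The share therefore cannot be read against chance. Of the 15 lymphocyte genes 12 were tested and 2 rose. Of the 14 neutrophil and mast cell genes only 6 were tested and 3 rose. No sort of the cells is given in the sources used here. Day and slide coincide, and a difference between the days in cells other than macrophages stays open as untested.

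Heart genes differed among the 4 day 9 arrays: the mean of the sarcomere list spanned 1.28 there, against 0.24 in mESC and 0.55 at day 14. An array effect that depends on signal was argued against, because 1000 random lists matched on signal had a median range of 0.08, which is 6.18% of that of the sarcomere list, and a highest range of 0.30. A different share of heart muscle cells as the sole cause was not decided. Of 18 lists for other cell types 5 moved with the sarcomere list and 5 against it. Gut (slope 0.58 ± 0.13) and visceral endoderm and liver genes (0.37 ± 0.08) moved with it, and blood (−0.81 ± 0.25) and fibroblast genes (−0.51 ± 0.08) against it. The SE of these slopes is taken over the genes of a list, which are not independent, on only 4 arrays. Sarcomere genes were left out, but 5 of the 14 gut genes also stood in another list. The counts therefore cannot decide the question. A share of several cell types that varied between the samples may remain, and it was not tested; the labels give no grouping of these 4 samples.

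Of the calls between the days 73.8% were higher, but the excess depended on the fold threshold, since without it 40.1% were higher (5305 higher, 7914 lower). The choice of scaling was argued against as the whole cause, since quantile normalization gave 66.7%, or 65.3% to 67.5% without any 1 array, and median scaling 77.6%. Dim probes on brighter arrays cannot be told apart from a difference between the days: among genes in the upper part by mean signal the share was 65.8% (455 higher, 237 lower), or 64.0% to 66.6% without any 1 array, so it lies on both sides of the bound of 65% set for that test. In the lower part by signal it was 76.4%. A biological difference between day 9 and day 14 stays open as untested.

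Further differences between the days were found. The list of ribosome biogenesis and Myc targets was lower at day 14 than at day 9 by a median of −0.48. Its adjusted p was 2.92e-05, and 0.0444 with an estimated correlation. No single member was called: Npm1 stood at −0.19 ± 0.04 and Ncl at −0.46 ± 0.04. Genes lower at day 9 and higher at day 14 against mESC numbered 77, and genes with the reverse pattern 7, each called between the days as well. Among the 77 were Ahsg (−4.60 and 5.25) and Ctss (−1.46 and 6.44), and among the 7 was Prtg (1.37 and −2.28).

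In 10 of 237 groups of 4 arrays, 1 array stood apart from the other 3, where chance gives about 11.8, or 1 in 20. The list mean of adipocyte genes was −1.97 in day 14 replicate 3 against −1.95 in the others, and that of cell cycle inhibitors and p53 targets was 2.09 in day 14 replicate 2 against 2.05. In mESC replicate 1 the mean of fatty acid oxidation genes was 1.43 against 1.47, of integrin and focal adhesion genes −0.37 against −0.33 to −0.32, of neural crest genes −2.57 against −2.66 to −2.64, and of the pluripotency network 3.43 against 3.48 to 3.49. The mean of polycomb and chromatin regulators was 2.32 in mESC replicate 2 against 2.28. In day 9 replicate 2 smooth muscle genes had a mean of 1.64 against 1.36 to 1.40, and Mesp1 stood at −4.96 against −4.38 to −4.31. Myl2 stood at −2.58 in mESC replicate 4 against −2.33 to −2.29.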

How the results depend on the processing

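The results, the alternatives and the 48 gene lists were set before the data were examined, and no alternative was added later. Normexp was changed from the planned mean signal to the median signal. The further macrophage, lymphocyte, and neutrophil and mast cell lists were added to the 48. The counts of called genes stayed within 1.5 times their value under quantile normalization, median scaling, the series table, no filter, the mean over probes, only the arrays compared, an intensity trend and array weights. With normexp they were 4750 at day 9 and 5835 at day 14 against mESC and 1226 between the days, with 3873 shared between both days. This setting changed the input signal, the background method and the offset together, and the cause was not tested. Named genes moved by a median of 1.62, 2.13 and 0.66 on the log2 scale, 23 of 207, 11 of 207 and 41 of 162 calls of named genes were lost with the sign kept, and those of Mesp1 (day 14 against mESC) and Hoxb1 (between the days) were lost as they turned from −1.17 and −1.69 to 0.023 and 0.159. On probes above background on all arrays, where 15894 genes were tested, 5483, 6430 and 1305 genes were called and 4611 were shared. Without a fold threshold, which admits smaller changes, they were 17398, 17765 and 13219, with 15035 shared, and 40.1% of those between the days were higher in place of 73.8%, and a test against a log2 fold change of 1 called 1519 between the days. With an estimated correlation 10 of the 78 list calls held, and the cause was not tested. Other settings called 67 to 93 of 144 lists, and no list call turned its direction in any setting. Some lists given as not called were called in 1 setting: at day 14 against mESC the neuron (adjusted p = 0.0215), endothelial (0.0178), neural progenitor (0.0398) and Notch lists (0.0478) with no filter and the glycolysis (0.0467) and stress lists (0.0417) with normexp, and between the days the sarcomere list (0.0469, lower) with normexp. Without 1 array the counts were 8541 to 8629, 9752 to 9800 and 2839 to 2925, and the calls among the 96 list tests that hold that array were 47 to 56. With the replicate number as a block they were 8562, 9780 and 2876 genes and 79 lists. Residual correlations of arrays with the same number were −0.02 to 0.02, −0.08 to 0.04 and −0.06 to 0.18, and their own number gave the highest in 1, 1 and 3 of 4. No pairing by number was seen against mESC, while between the days it stays open. Replicate number was also the place on the slide, so these cannot be told apart. Signal over background limits the fold changes of dim genes, and 59.5% to 67.9% of probes were well above it.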

Other observations

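Lists of signalling pathways and of regional identity were tested against mESC. Wnt pathway genes rose in 16 of 23 cases at day 9 and 2 fell (adjusted p = 0.000245, and adjusted p = 0.0417 with an estimated correlation). The receptor gene Fzd1 stood at 6.56 ± 0.10 and the inhibitor Dkk1 at 5.89 ± 0.15. Genes of the BMP and TGF-beta pathway rose in 19 of 27 cases and 3 fell (adjusted p = 3.92e-05, and adjusted p = 0.0417 with an estimated correlation). Id3 stood at 6.46 ± 0.13 and Bmp4 at 5.37 ± 0.09. The Notch list was not called (adjusted p = 0.379 at day 9 and 0.18 at day 14), although Hey1 was 2.88 ± 0.15 higher at day 9. Retinoic acid pathway genes rose in 8 of 14 cases at day 9 and 2 fell (adjusted p = 0.0174, and adjusted p = 0.143 with an estimated correlation), with the receptor gene Rarb at 6.65 ± 0.06. Between the days 6 of these 14 rose (adjusted p = 0.00151, and adjusted p = 0.0582 with an estimated correlation), Aldh1a1 by 5.65 ± 0.09. Hox genes rose in 12 of 25 cases at day 9 and 3 fell (adjusted p = 0.0082, and adjusted p = 0.474 with an estimated correlation), and on probes above background on all arrays the list was not called (adjusted p = 0.0745). Hoxb3 rose by 7.28 ± 0.10 and Hoxb2 by 5.96 ± 0.15. Imprinted genes rose in 14 of 18 cases at day 9 and 2 fell (adjusted p = 3.15e-05, and adjusted p = 0.157 with an estimated correlation), with Dlk1 at 8.94 ± 0.11 and Peg3 at 6.23 ± 0.07. Of the immediate early genes 6 of 15 were called higher and 3 lower at day 9 (adjusted p = 0.203), Jun at 4.84 ± 0.05. Polycomb and chromatin regulators fell in 13 of 20 cases at day 14 and 2 rose (adjusted p = 0.00501, and adjusted p = 0.134 with an estimated correlation), with Dnmt3l at −5.42 ± 0.26 and Cbx7 at −3.90 ± 0.05.

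Further lists covered metabolism and stress. Genes of oxidative phosphorylation fell in 4 of 28 cases at day 14 and 2 rose (adjusted p = 0.0267, and adjusted p = 0.58 with an estimated correlation), and the list was not called with quantile normalization (adjusted p = 0.977), median scaling (adjusted p = 0.062) or probes above background on all arrays (adjusted p = 0.0623). The heart and muscle subunits Cox8b and Cox6a2 rose by 6.55 ± 0.51 and 2.09 ± 0.27. Fatty acid oxidation genes rose in 4 of 20 cases between the days (adjusted p = 0.0212, and adjusted p = 0.23 with an estimated correlation), with Cd36 at 4.05 ± 0.21 and Cpt1a at 1.48 ± 0.10, and the list was not called with normexp (adjusted p = 0.209) or without day 9 replicate 1 (adjusted p = 0.0536). The glycolysis list (adjusted p = 0.264 at day 14), the list of cell cycle inhibitors and p53 targets (0.917) and the list of endoplasmic reticulum stress and heat shock (0.298) were not called. Among their genes the muscle enzyme gene Pgam2 was 4.36 ± 0.25 higher, the inhibitor gene Cdkn1c 6.89 ± 0.11 higher, and Hspb1 stood at −2.18 ± 0.05.

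Markers of further cell types were mixed at day 14 against mESC. In the neural progenitor list 9 of 17 were called higher and 4 lower (adjusted p = 0.145), and Fabp7 was at least 167-fold higher. Glia genes rose in 5 of 10 cases and 1 fell (adjusted p = 0.0401, and adjusted p = 0.23 with an estimated correlation), S100b by 3.74 ± 0.17, but the list was not called in 5 of 19 alternatives (adjusted p up to 0.105, with the mean over probes). The neural crest list had 7 genes higher and 3 lower of 14 (adjusted p = 0.236), with Snai2 at 3.99 ± 0.16. In the surface epithelium list 10 of 19 were called higher and 4 lower (adjusted p = 0.151), with the keratin genes Krt15 and Krt14 at 4.71 ± 0.14 and 4.69 ± 0.14 and the epithelial cadherin gene Cdh1 at −4.02 ± 0.17. For trophoblast genes these numbers were 9 and 4 of 14 (adjusted p = 0.117), with Tpbpa at least 67.2-fold higher. For bone and cartilage genes they were 6 and 5 of 14 (adjusted p = 0.324), with Alpl at −5.04 ± 0.13. Spp1 was −8.55 ± 0.19 at day 9 against mESC and 6.96 ± 0.19 higher at day 14 than at day 9. Skeletal muscle genes rose in 6 of 17 cases between the days and 1 fell (adjusted p = 0.00151, and adjusted p = 0.15 with an estimated correlation), the muscle factor gene Myog by at least 8.76-fold and Myh3 by 3.38 ± 0.23. With normexp this list was not called (adjusted p = 0.0514).

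The 10 spike-in transcripts had a mean log2 signal of 9.48 ± 0.13 (SD, n = 4) on the mESC arrays, 9.25 ± 0.25 at day 9, with 1 array at 8.89, and 9.33 ± 0.13 at day 14. The SD between arrays of probes spotted 10 times was 0.0585 in mESC, 0.133 at day 9 and 0.0634 at day 14.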
